A study of Danio rerio with 16 samples.

How the data were processed

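Whole zebrafish (Danio rerio) embryos were profiled by sequencing of total RNA on a DNBseq-G50 instrument, per the labels. The 16 libraries fall into 4 groups of 4 replicates: unexposed controls and embryos exposed to radiofrequency radiation (RFR) at 3.5 GHz and about 30 dBm from 6 to 48 hours post fertilization (hpf), each collected at 48 or at 120 hpf. The labels do not say how many embryos went into a library or whether replicates came from separate clutches, so p-values measure only the spread between these libraries, which may be technical.

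The expression values are FPKM (fragments scaled to transcript length and to the library's mapped total), per the file headers, deposited by the authors with 2 decimals for 32513 rows. The submitters' processing notes name HISAT2, Bowtie2, DESeq2 and the build GRCz11, with no version, role or order. The program that made the FPKM values is not given in the sources used here. The authors' deposited summaries give counts of reads after filtering and counts of genes detected for each library, per the file headers. They also give, in percent, the reads kept by the filter, the rRNA share, the bases at quality 30 or above and the reads mapped, per the file headers. The table has no mitochondrially encoded genes under the symbols looked for. It lists 6349 rows without a gene symbol, and rows of noncoding RNA are given per transcript, so variants of a locus stand in separate rows.

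All tests start from the deposited FPKM values, which are not counts, so no count model was used. The planned test for tables without counts was applied: limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with a mean-variance trend, for the 23026 genes at 0.5 FPKM or more in at least 4 libraries. All libraries entered 1 fit of group means with 12 residual degrees of freedom. Fold changes are on this log2(FPKM + 0.5) scale, which understates the change of genes at low level. P-values are two-sided and Benjamini-Hochberg adjusted, and a gene counted as changed at an adjusted p under 0.05. The comparisons were RFR against control at 48 hpf, RFR against control at 120 hpf, the difference between these effects, and 120 against 48 hpf in controls.

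Gene lists for stress responses, metabolism, the clock and the organs of the embryo were written before the data were examined, as were the test, the named-gene rule and most other settings tried. Of 29 lists, 28 had at least 5 tested members. The list of mitochondrially encoded genes had 0. Members were matched by the table's symbols for 1223 entries. Another 65 matched through current symbols and 5 through synonyms of an NCBI RefSeq gene table (assembly GRCz12tu, used for names only), and 46 entries stayed unmatched. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a comparison. Camera compares the genes of a list with all other tested genes. A list called lower or higher is so relative to them, and need not differ between RFR and control by itself. Camera with an estimated correlation and limma's fry, which tests a list's own difference, served as checks. Gene Ontology (GO) biological process terms of 10 to 300 genes were tested in the same way as a separate family, added after the data were seen. The planned test of KEGG pathways did not apply, because the table gives KEGG orthology terms without pathways.

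For each RFR comparison the rule named the 10 largest rises and falls among changed genes with a symbol and a mean of at least 1 FPKM. Where fewer than 5 passed in a direction it named the 5 smallest p instead. It also named the 3 members with the smallest p in each list called by camera, and in the heat shock, oxidative stress, p53, clock and stress axis lists in any case. For development it named the 10 largest rises and falls with a group mean of at least 50 FPKM.

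Data were simulated from the real means and limma's estimates of the spread, with independent normal noise. The changed genes were drawn among those with a mean of at least 1 FPKM. For the 48 hpf comparison (23026 genes, 100 changed at each size), 85% of 2-fold and 43% of 1.5-fold changes were recovered, with 6 false calls among 134. For the 120 hpf comparison the shares were 86% and 56%, with 5 false calls among 147. Camera called 0 of 28 lists when independent genes were simulated without change. In the real data the estimated correlation was 0.744 for the cell cycle list and 0.548 for ribosomal proteins. The simulation therefore does not show how often camera calls unchanged lists of correlated genes. Nor does it show limma's recovery and false calls where genes vary together or lie at low level.

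Raw read totals were 47.48 M in every library with replicate number 1 to 3 and differed in every replicate 4, which were therefore treated as a separate batch of 1 library per group. Fits on replicates 1 to 3 only and with replicate 4 as a batch term were added after the data were seen. The other settings, chosen before the data were examined, were the replicate number as a block, quantile normalization, median-ratio scaling, no filter, a filter at 5 FPKM, pseudocounts of 0.1 and 1, no trend, library weights, an adjusted p under 0.1, only the groups compared, and each library left out in turn. No coordinates are given, because the reference table is of another build than the one named in the submitters' notes.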

Results

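The series asks whether exposure of zebrafish embryos to 3.5 GHz radiofrequency radiation (RFR), a frequency band used by 5G telephony, alters gene expression at the end of the exposure (48 hpf) and 72 h later (120 hpf). RNA of whole embryos was measured in 4 control and 4 RFR libraries at each stage. Depth after the authors' filter lay between 39603976 and 49232542 reads per library. Of these, 69.4 to 71.8% mapped at 48 hpf and 66.2 to 67.6% at 120 hpf. The rRNA share was 3.2% in control 120 hpf replicate 1 and 0.15 to 0.30% in the other libraries. For the median gene, the 95% confidence interval of an RFR fold change reached 0.306 log2 units to either side, or 1.24-fold.

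Developmental stage set the libraries apart. The first principal component held 83.1% of the variance and separated 48 from 120 hpf. On it RFR 48 hpf replicates 2 to 4 (-86.41, -76.93 and -86.75) lay nearer to 120 hpf than the 48 hpf controls (-101.5 to -91.16), while RFR replicate 1 (-100.5) lay among these. At 120 hpf RFR replicates 2 (98.94) and 3 (94.58) lay beyond the controls (86.16 to 93.34) and RFR replicates 1 and 4 among them. Correlation coefficients across genes had a median of 0.980 between libraries of a group (24 pairs) and 0.979 between control and RFR libraries of the same stage (32 pairs). Between stages the median was 0.809 (64 pairs). Genes are not independent replicates, so these coefficients only describe the libraries.

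**Figure D1:**
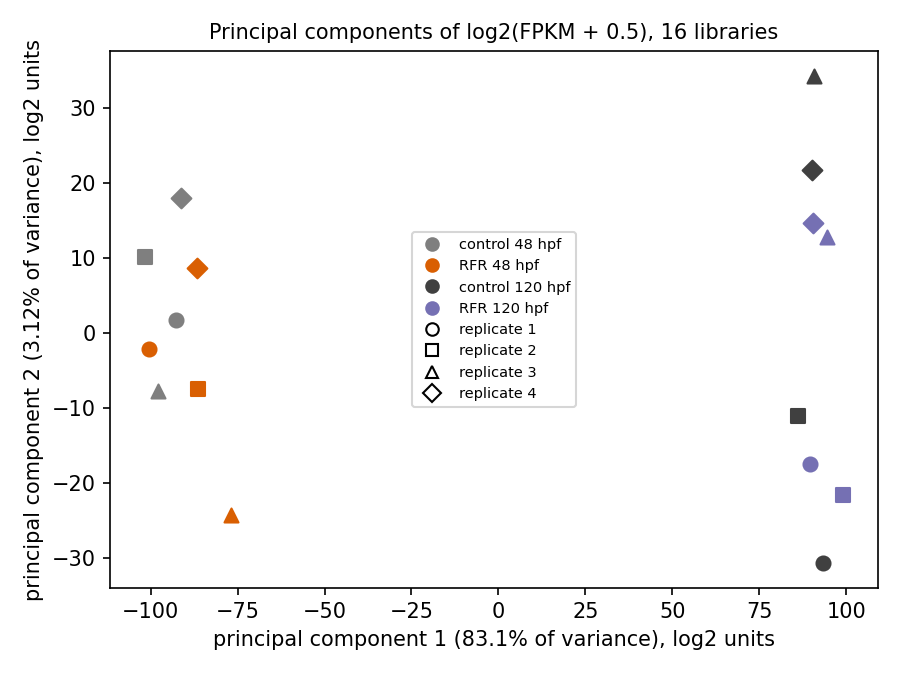
Principal components 1 and 2 of log2(FPKM + 0.5) over the 23026 tested genes, in log2 units, with 1 point per library, colours for the 4 groups and symbols for replicate numbers. Component 1 (83.1% of the variance) parts the stages, and component 2 (3.12%) does not part control from RFR libraries.

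At 48 hpf, the end of the exposure, almost no single gene passed the test. The 1 gene called was a noncoding transcript, XR_659546.2 (variant X2 of the uncharacterized locus LOC103909570), which has no symbol, lies outside the named-gene rule and is named here after its values were seen. It stood at 3.96, 2.28, 4.48 and 0.92 FPKM in control replicates 1 to 4 and was listed at 0 in all RFR 48 hpf libraries and in all libraries at 120 hpf (limma adjusted p = 0.0015). The spread behind that p is pooled with the groups listed at 0 throughout. With only the 2 groups compared, the limma adjusted p was 0.28. The transcript passed the filter only through the control 48 hpf libraries. Among genes with a symbol, those with the smallest p were not past the threshold. The homeobox genes hmx4 and otx5 had the higher means in RFR embryos: hmx4 10.8 ± 1.27 FPKM in controls and 16.1 ± 0.76 in RFR (SD, n = 4 each; limma adjusted p = 0.213), and otx5, a factor of retina and pineal gland, 19.3 ± 4.87 and 34.6 ± 7.51 (adjusted p = 0.235). The mitochondrial deacetylase sirt3 had a log2 fold change of 0.62 ± 0.116 (SE), the uncharacterized si:dkey-92j12.6 0.55 ± 0.109 and the RNA-binding protein gene rbpms2b 0.37 ± 0.072, each at an adjusted p of 0.235. On the lower side were shmt1, a serine hydroxymethyltransferase of folate metabolism, at 39.7 ± 5.26 FPKM in controls and 26.9 ± 1.08 in RFR (adjusted p = 0.213), and ctss2.1, a cathepsin S gene, at 7.54 ± 1.17 and 2.94 ± 0.572 (adjusted p = 0.25). LOC100537272, predicted to be a mannose receptor, had a log2 fold change of -0.60 ± 0.108 (adjusted p = 0.235). For rbp4l, a retinol-binding protein gene, and mmp30, a matrix metallopeptidase gene, the values were -0.71 ± 0.159 and -0.34 ± 0.079 (both 0.25).

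Of the 23026 genes, 2180 had an unadjusted p under 0.05 at 48 hpf, 1680 with the higher mean in RFR and 500 with the lower, where 1151 would be reached by chance. Other splits of these libraries gave between 332 and 3406. The lean to higher means may depend on scaling. The median fold change of all genes was 0.0426 log2 units, 0.000887 after quantile normalization (1726 genes at an unadjusted p under 0.05) and -0.00528 after median-ratio scaling (1967). The count of called genes depended on RFR replicate 1. Without it, limma called 389 genes, 350 higher and 39 lower, among them 9 of the 10 genes named by smallest p above (adjusted p from 0.00709 to 0.0485). Without control replicate 2 it called 3, among them hmx4 and shmt1 (adjusted p = 0.0427 for both). With library weights 8 genes were called (3377 at an unadjusted p under 0.05), and limma on only the libraries of this stage called 0 (1986). Within the batch of replicates 1 to 3 it was 1 gene, as with replicate 4 as a batch term.

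Gene lists of differentiated neurons and of the lens lay higher in RFR embryos at 48 hpf. Of 59 neuron and synapse genes, 54 had a positive fold change, with a median of 0.26 log2 units (camera adjusted p = 4.64e-12; adjusted p = 0.545 with an estimated correlation). No member passed over all genes tested, while 8 rose when adjusted over the list alone. The vesicular GABA transporter slc32a1 stood at 15.8 ± 1.22 FPKM in controls and 20.1 ± 2.04 in RFR (SD, n = 4; limma adjusted p = 0.25), the neuronal RNA-binding protein elavl4 at 70.9 ± 8.76 and 92.1 ± 12.6 (0.257), and the synaptic vesicle protein vamp2 at 16.1 ± 2.83 and 23.0 ± 2.45 (0.263). Of 64 lens genes, 57 had a positive fold change, with a median of 0.33 (camera adjusted p = 1.33e-11; adjusted p = 0.796 with an estimated correlation), and 8 rose when adjusted over the list alone. The gamma crystallins crygmx, crygm2d15 and crygmxl2 had log2 fold changes of 0.33 ± 0.087, 0.79 ± 0.217 and 0.47 ± 0.141 (SE), at limma adjusted p of 0.257, 0.267 and 0.295. Crystallin copies are similar in sequence, so their reads could be split between them. Calcium channel and calcium handling genes were called higher too, 53 of 65 with a positive fold change and a median of 0.12 (camera adjusted p = 0.00469; adjusted p = 0.796 with an estimated correlation). That median was 0.079 after quantile normalization and 0.069 after median-ratio scaling. The kinases camk2d2 and camk2b1 and the calcium-binding protein calb1 had log2 fold changes of 0.33, 0.24 and 0.26 (limma adjusted p = 0.265, 0.288 and 0.329). Without RFR replicate 1, slc32a1, elavl4, crygm2d15, crygmxl2 and camk2d2 passed over all genes (limma adjusted p = 0.0236, 0.0196, 0.000576, 0.0227 and 0.0239).

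Ribosomal protein genes, cell cycle genes and heat shock genes were called lower at 48 hpf. All but 1 of the 77 ribosomal protein genes had a negative fold change, with a median of -0.16 log2 units (camera adjusted p = 1.47e-33; adjusted p = 0.545 with an estimated correlation). Examples were rps2 at 2483 ± 134 FPKM in controls and 2128 ± 143 in RFR (SD, n = 4; limma adjusted p = 0.291) and rpl5b at 1155 ± 70.9 and 1008 ± 62.1 (0.322). The exception, rps8b, was expressed at 1.43 ± 0.226 and 2.38 ± 0.422 FPKM (0.25) and was the 1 member to rise when adjusted over the list alone. The median was -0.038 after quantile normalization and -0.22 after median-ratio scaling. Among 33 cell cycle genes 29 had a negative fold change, median -0.14 (camera adjusted p = 6.57e-06; adjusted p = 0.796 with an estimated correlation). Without RFR replicate 3 the median was -0.049 (camera adjusted p = 0.0131). The replication licensing factors mcm7 and mcm4 and cyclin D1 (ccnd1) had log2 fold changes of -0.33, -0.39 and -0.27 (limma adjusted p = 0.424, 0.486 and 0.526). Of 36 heat shock and chaperone genes 29 had a negative fold change, median -0.13 (camera adjusted p = 6.57e-06; adjusted p = 0.545 with an estimated correlation). Without control replicate 1 it was -0.067 (camera adjusted p = 0.00238). The inducible chaperones hsp90aa1.1 and hsp70.3 stood at 77.1 ± 34.6 and 25.5 ± 10.4 FPKM in controls and at 41.9 ± 8.39 and 11.2 ± 3.44 in RFR (limma adjusted p = 0.328 and 0.399), and the cochaperone dnajb1b had a log2 fold change of -0.49 (0.356).

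The remaining lists called lower at 48 hpf, relative to the other genes tested, were those of erythroid cells, sterol synthesis, the liver and fatty acids. The median of all genes was 0.0426 log2 units. Fry, which does not compare with other genes, gave an unadjusted p of 0.357, 0.652, 0.807 and 0.794 for these lists in that order. In erythroid cells 23 of 29 genes had a negative fold change (median -0.14, camera adjusted p = 0.00195; adjusted p = 0.796 with an estimated correlation), among them blvrb at -0.27, the embryonic globin hbbe3 at -0.60 and gata1a at -0.50 log2 units (limma adjusted p = 0.581, 0.606 and 0.626). Sterol synthesis had 19 of 26 negative (median -0.10, camera adjusted p = 0.036; adjusted p = 0.796 with an estimated correlation), with ebp at -0.55 and fdps at -0.22, while the receptor gene ldlra was at 0.52 (limma adjusted p = 0.682, 0.685 and 0.355). In the liver list 30 of 47 were negative (median -0.093, camera adjusted p = 0.036; adjusted p = 0.796 with an estimated correlation), but its members with the smallest p, c3a.3, hpda and fabp10a, had positive log2 fold changes of 0.81, 0.73 and 0.75 (limma adjusted p = 0.296, 0.328 and 0.344). The fatty acid and lipoprotein list had a median of -0.0027 with 27 members on either side (camera adjusted p = 0.0482; adjusted p = 0.796 with an estimated correlation); apoa4b.3 was at -1.53 and apoeb at -0.41 (limma adjusted p = 0.257 and 0.372). Leaving out single libraries ended these calls: the erythroid call without control replicate 2 (camera adjusted p = 0.0513) or RFR replicate 4 (0.199), and the liver call without control replicate 1 (0.327) or 4 (0.279) or RFR replicate 1 (0.931) or 2 (0.406). The sterol call was lost without control replicate 3 (0.0799) or 4 (0.168) or RFR replicate 1 (0.125), 2 (0.102) or 3 (0.139), and the fatty acid call without control replicate 1 (0.127), 3 (0.098) or 4 (0.189) or RFR replicate 1 (0.505) or 2 (0.149). Quantile normalization and median-ratio scaling ended the sterol (camera adjusted p = 0.0581 and 0.0582), liver (0.184 and 0.0856) and fatty acid (0.184 and 0.0588) calls. On replicates 1 to 3 only the erythroid (0.0659) and fatty acid (0.0547) calls were lost, the latter also with the batch term (0.0585). Without single libraries the erythroid median shrank to -0.071 (control replicate 2) and -0.023 (RFR replicate 4), and the sterol median to -0.053 (control replicate 3), -0.064 (RFR replicate 2) and -0.037 (RFR replicate 3). The liver median shrank to -0.036 and -0.023 (control replicates 1 and 4) and -0.0057 (RFR replicate 1) and turned positive, 0.0097, without RFR replicate 2. The fatty acid median turned positive without control replicate 1 (0.0014), 3 (0.0095) or 4 (0.029) or RFR replicate 1 (0.026) or 2 (0.0043). Leaving out other libraries moved a median away from 0: liver to -0.14, -0.18 and -0.24 without control replicate 3, RFR replicate 3 and RFR replicate 4, fatty acids to -0.032, -0.062 and -0.059 without control replicate 2, RFR replicate 3 and RFR replicate 4, and sterol synthesis to -0.18 without RFR replicate 4.

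Lists fixed for stress responses other than heat shock were not called at 48 hpf. Camera gave an adjusted p of 0.22 for oxidative stress (hmox1a -0.81, gpx1b 0.47 and txn -0.24 log2 units), 0.17 for p53 and DNA damage (plk3 -0.29, gadd45aa 0.33, sesn2 -0.42), 0.177 for clock and light-regulated genes (aanat2 0.64, rorab 0.57, cry-dash 0.39) and 0.997 for the stress axis (pomcb -0.51, egr3 0.38, egr1 0.32). The smallest limma adjusted p among these genes was 0.312, for aanat2; without RFR replicate 1, rorab (0.00317) and plk3 (0.0414) passed and camera called the clock list (adjusted p = 0.0261). In all, camera called 10 of 28 lists, 3 higher and 7 lower. With an estimated correlation it called 0, and fry called 0 (lowest adjusted p = 0.182). On replicates 1 to 3 only, 9 lists were called, as with the batch term.

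**Figure D2:**
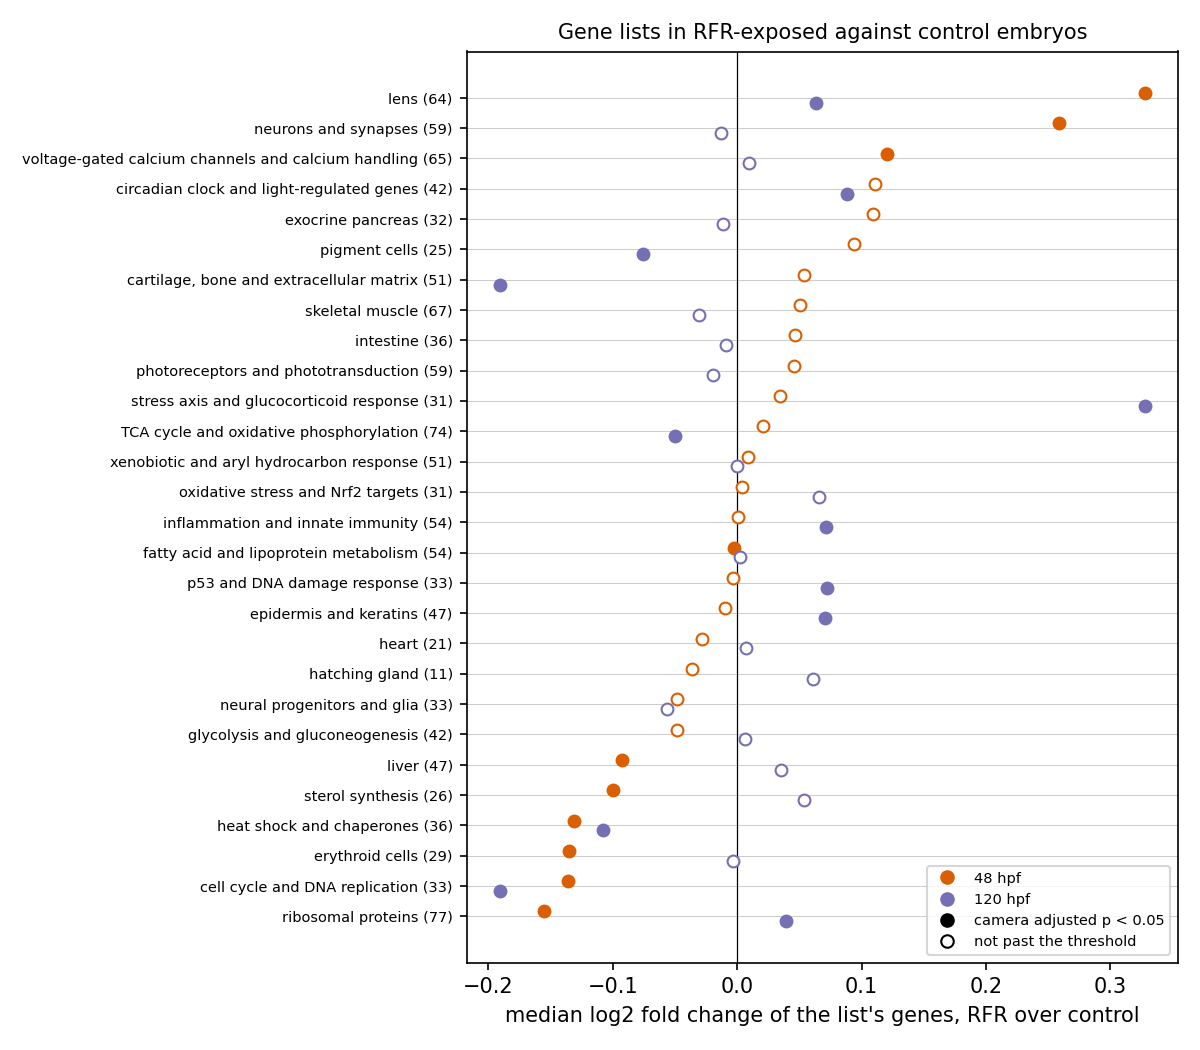
Median log2 fold change (RFR over control) of each of the 28 gene lists at 48 hpf (orange) and 120 hpf (purple), with the number of tested genes in brackets and filled points for a camera adjusted p under 0.05 at the preset correlation. Lens (0.33) and neurons (0.26) lie highest at 48 hpf, ribosomal proteins (-0.16) lowest, and the stress axis (0.33) lies highest at 120 hpf.

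At 120 hpf, 72 h after the exposure ended, 0 genes passed limma's test, and 952 had an unadjusted p under 0.05 (410 higher, 542 lower in RFR; 1151 by chance). Within replicates 1 to 3 and with the batch term the count was also 0, but with the replicate block it was 1, LOC100007069 (log2 fold change 1.79, limma adjusted p = 0.0131), and without a filter 4. The latter were ungb and the noncoding transcripts XR_002456116.1, XR_002457447.1 and XR_002455757.1; all 5 lie outside the named-gene rule and are named after their values were seen. The genes with the smallest p, none past the threshold, included gadd45bb, a stress-inducible growth arrest gene, at 5.42 ± 1.18 FPKM in controls and 9.80 ± 0.897 in RFR (SD, n = 4; limma adjusted p = 0.149). At the same adjusted p were snu13a, a small nuclear ribonucleoprotein gene, at 3.04 ± 0.732 and 5.43 ± 0.562 FPKM, and the uncharacterized si:ch73-141c7.1 at 14.7 ± 1.44 and 20.9 ± 0.896. The transcription factor nfil3 and the tight junction gene cldnb had log2 fold changes of 0.34 ± 0.069 and 0.49 ± 0.103 (SE; adjusted p = 0.371 and 0.388). On the lower side ddx43, zc2hc1c, wdr33, mettl21a and and1 had log2 fold changes of -1.20, -0.98, -0.28, -0.50 and -0.40, at adjusted p of 0.371, 0.371, 0.388, 0.506 and 0.522.

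The list called with the highest median at 120 hpf was the stress axis and glucocorticoid response (0.33 log2 units, 23 of 31 genes with a positive fold change, camera adjusted p = 5.49e-09; adjusted p = 0.319 with an estimated correlation), and the median was 0.50 without RFR replicate 4. The 6 members that rose when adjusted over the list alone did not pass over all genes. Its members with the smallest p are immediate-early genes, which answer many stimuli and are not specific to cortisol: ier2a at 17.6 ± 6.69 FPKM in controls and 27.9 ± 2.78 in RFR (SD, n = 4; limma adjusted p = 0.883), junbb at 19.5 ± 6.26 and 31.8 ± 6.18 (0.883) and npas4a at 9.48 ± 6.92 and 19.9 ± 4.47 (0.909). The p53 and DNA damage list was called higher as well, 23 of 33 positive, median 0.072 (camera adjusted p = 0.00044; adjusted p = 0.319 with an estimated correlation), with gadd45bb, plk2b (0.32 log2 units, limma adjusted p = 0.754) and gadd45ba (0.86, adjusted p of 1). Its median was 0.034 without control replicate 2 (camera adjusted p = 0.00243), 0.025 without RFR replicate 3 (0.0277) and 0.14 without RFR replicate 4 (9.98e-05). Inflammation genes had a median of 0.071 (camera adjusted p = 0.0179; adjusted p = 0.928 with an estimated correlation), with socs3a at 1.21, mmp9 at 0.50 and socs3b at 0.42. The inflammation call was lost without control replicate 1 (camera adjusted p = 0.181), 2 (0.0646) or 4 (0.131) or RFR replicate 2 (0.0562) or 3 (0.849, with a median of -0.028), and its median was 0.042 and 0.036 without control replicates 1 and 4, 0.12 without RFR replicate 2, and 0.21, 0.15 and 0.17 without control replicate 3, RFR replicate 1 and RFR replicate 4. Replicate 4, the separate batch, had the lowest stress axis mean in both groups.

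Cartilage, bone and extracellular matrix genes were called lower at 120 hpf: 43 of 51 had a negative fold change, with a median of -0.19 (camera adjusted p = 4.86e-11; adjusted p = 0.434 with an estimated correlation), and 2 fell when adjusted over the list alone. The fin fold structural gene and1 had a log2 fold change of -0.40 ± 0.093 (SE; limma adjusted p = 0.522). The related and3 stood at 157 ± 5.05 FPKM in controls and 130 ± 10.6 in RFR (SD, n = 4; limma adjusted p = 0.602), and the collagen gene col11a1b at 23.0 ± 1.52 and 18.4 ± 1.52 (0.909). Of 33 cell cycle genes 32 had a negative fold change (median -0.19, camera adjusted p = 7.2e-07; adjusted p = 0.856 with an estimated correlation), with tyms, mcm2 and bub1 at -0.53, -0.40 and -0.29. Without RFR replicate 2 the call was lost (median -0.030, camera adjusted p = 0.375), and the median was -0.12 without control replicate 3, -0.29 without control replicate 1 and -0.31 without RFR replicate 3. Heat shock genes were again called lower, 26 of 36 negative, median -0.11 (camera adjusted p = 0.00117; adjusted p = 0.776 with an estimated correlation), with the collagen chaperone serpinh1b at -0.64, ahsa1a at -0.59 and hspb1 at -0.24. Without RFR replicate 2 its median was -0.0043 and the call was lost (camera adjusted p = 0.148), and without RFR replicate 3 it was -0.19.

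The other lists called at 120 hpf had medians between -0.076 and 0.088. Called higher were ribosomal proteins (median 0.039; rpl38 0.20, rpl7 0.092 and rps20 0.11), the clock (0.088; nfil3, nfil3-5 at -0.18 and nfil3-6 at 0.35), epidermis (0.071; cldnb, krt95 at -0.38 and foxi3a at 0.39) and lens (0.063; lim2.2 at 0.56, crygm2f at -0.77 and crygm1 at 0.46). Called lower were the tricarboxylic acid cycle and oxidative phosphorylation (-0.050; ndufb5 -0.17 and idh3a -0.24) and pigment cells (-0.076; aox5 -0.41, oca2 -0.27 and gch2 -0.36). With an estimated correlation, adjusted p was 0.963, 0.791, 0.319, 0.963, 0.963 and 0.856 for these lists in the order given. Each of these calls depended on single libraries, and some on other settings. The ribosomal call was lost without control replicate 1 (camera adjusted p = 0.127) or 2 (0.0646) or RFR replicate 4 (0.0849), the clock call without RFR replicate 2 (0.137), and the epidermis call without control replicate 1 (0.152) or RFR replicate 2 (0.137) or 4 (0.0763). The lens call was lost without control replicate 1 (0.0541), 2 (0.0998) or 3 (0.244) or RFR replicate 1 (0.0942), 2 (0.295) or 4 (0.726). The tricarboxylic acid cycle call was lost without control replicate 2 (0.118) or 3 (0.47) or RFR replicate 1 (0.143), 2 (0.469) or 4 (0.0849), and the pigment call without control replicate 1 (0.124), 2 (0.172) or 4 (0.0654) or RFR replicate 2 (0.112) or 3 (0.849). Quantile normalization ended the lens (0.0569), tricarboxylic acid cycle (0.213) and pigment (0.112) calls. On replicates 1 to 3 only the lens call (0.117) was lost and the tricarboxylic acid cycle list lay at the threshold (0.05, not called), and the pigment call was lost with only the groups compared (0.0747) and with the batch term (0.0504). Where a call was lost, the tricarboxylic acid cycle median shrank to -0.024 without control replicate 3 and turned positive, 0.0063, without RFR replicate 2, and the pigment median shrank to -0.045 (control replicate 2) and -0.0093 (RFR replicate 3). The ribosomal median was then 0.022 and 0.024 (control replicates 1 and 2), that of the clock 0.056 (RFR replicate 2), of epidermis 0.040 (control replicate 1) and 0.035 (RFR replicate 2), and of lens 0.040 (control replicate 3), 0.034 and 0.025 (RFR replicates 2 and 4). With the call kept, the pigment median moved to -0.13 without control replicate 3, -0.12 without RFR replicate 1 and -0.11 without RFR replicate 4, and the tricarboxylic acid cycle median to -0.078 without control replicate 1 and -0.12 without RFR replicate 3. The epidermis median was 0.043 without control replicate 3 and the lens median 0.15 without RFR replicate 3. The oxidative stress list was not called (camera adjusted p = 0.368, or 0.0432 without RFR replicate 2; sod1 -0.27, gstp2 -0.57 and hmox1a 0.58). Camera called 12 of 28 lists, 7 higher and 5 lower, against 0 with an estimated correlation and 0 by fry (lowest adjusted p = 0.794). Without control replicate 2 or RFR replicate 2 it called 7, on replicates 1 to 3 only 10, and with the batch term 11. Without control replicate 1 it called 8.

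**Figure D3:**
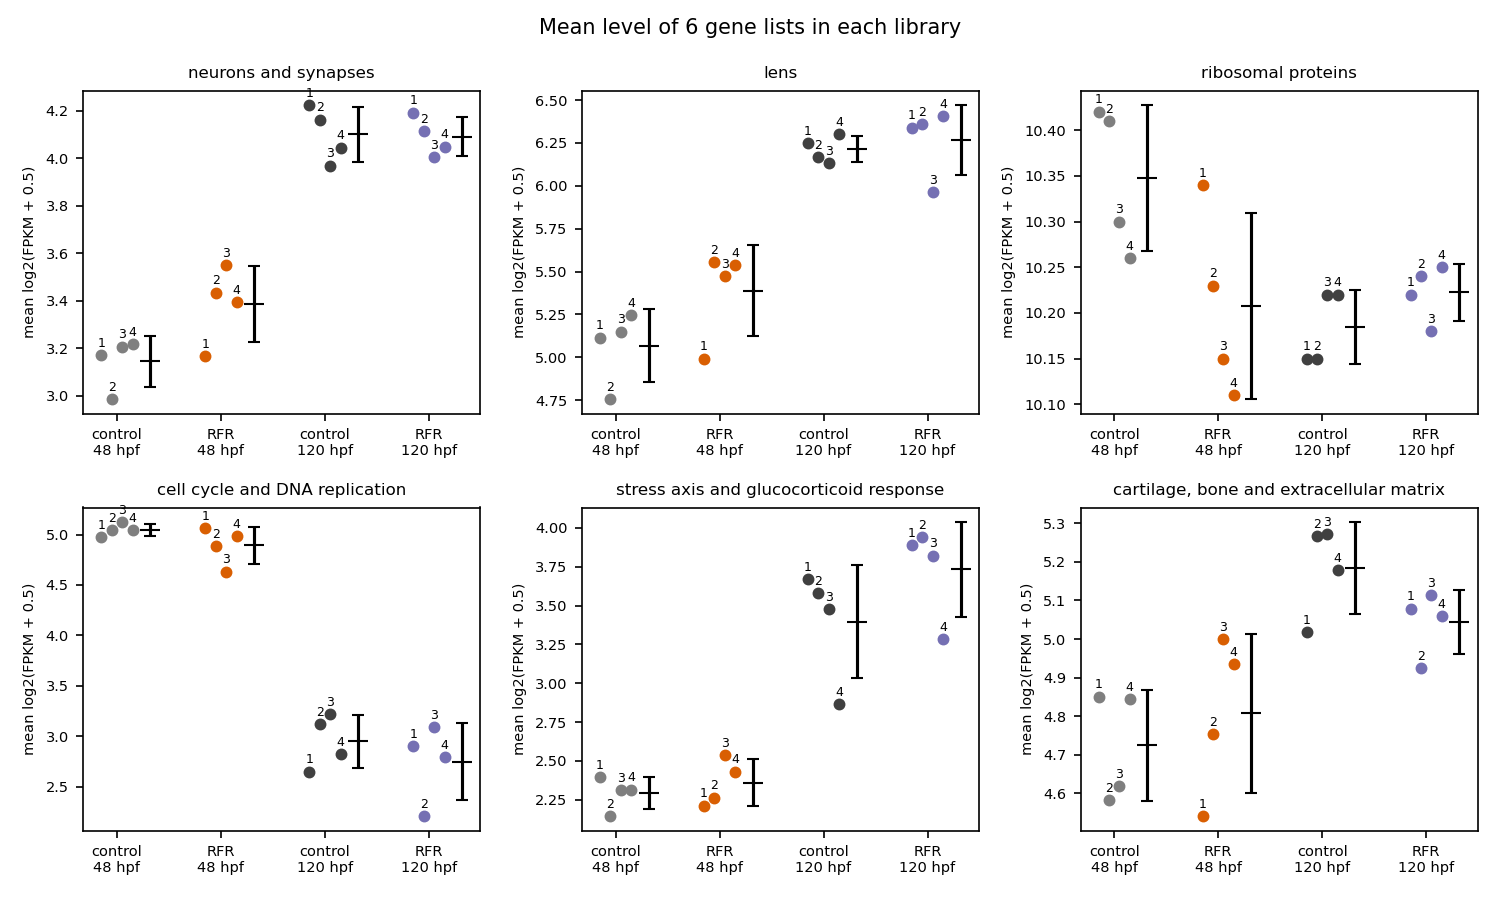
Mean log2(FPKM + 0.5) of the members of 6 gene lists in each library (points, numbered by replicate) for the 4 groups, with the mean and SD of each group as bar and whiskers beside the points. In the neuron and lens panels RFR 48 hpf replicate 1 (3.17 and 4.99) lies among the controls, and in the stress axis panel replicate 4 lies lowest in both 120 hpf groups.

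The RFR effects of the 2 stages were compared directly in the same fit. Limma found 0 genes whose effect differed between 48 and 120 hpf (lowest adjusted p = 0.128), and 1575 had an unadjusted p under 0.05. Without control 48 hpf replicate 4 or RFR 48 hpf replicate 1 it found 1 gene, as on replicates 1 to 3 only, and with the batch term 0. Across genes the log2 fold changes of both stages had a Pearson coefficient of 0.0289 and a Spearman coefficient of 0.0524, with the same sign for 50.7% of genes. Among the lists, camera called 13 of 28 as differing, 0 with an estimated correlation. The ribosomal protein list moved up from 48 to 120 hpf relative to controls (median difference 0.19, 75 of 77 positive, camera adjusted p = 6.06e-30, and 0.338 with an estimated correlation). Its 48 hpf median was -0.038 after quantile normalization and -0.22 after median-ratio scaling, so the size of this difference may depend on scaling. The neuron list moved down (median difference -0.24, 55 of 59 negative, camera adjusted p = 3.53e-09; adjusted p = 0.553 with an estimated correlation).

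Normal development between the stages changed most genes. In controls, 15227 of 23026 genes changed (66.1%), 8811 up and 6416 down, of which 4198 rose and 1861 fell by over 2-fold. This balance depends on scaling: 6336 rose and 8906 fell after quantile normalization, where the median of all genes moved from 0.124 to -0.139 log2 units, and 7873 rose and 7486 fell after median-ratio scaling. The pancreatic digestive enzymes came on, with 29 of 32 exocrine pancreas genes up and a median rise of 8.25 log2 units. The trypsin gene try went from 1.25 ± 0.529 to 2935 ± 258 FPKM and chymotrypsinogen ctrb1 from 0.393 ± 0.38 to 3047 ± 281 (SD, n = 4; limma adjusted p = 5.19e-15 and 5.86e-14). The proteases prss59.2, prss59.1, ctrl, zgc:92041, ela2l, zgc:136461 and c6ast4 rose by between 10.19 (zgc:136461) and 12.16 (prss59.2) log2 units. The ultraviolet cone opsin opn1sw1 rose from 0.333 ± 0.375 to 833 ± 52.4 FPKM (adjusted p = 6.95e-16), as did 52 of 59 photoreceptor genes.

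Intestine genes rose in 28 of 36 cases (median 4.37) and xenobiotic response genes in 44 of 51 (median 2.25). Neuron genes rose in 46 of 59 cases and lens genes in 50 of 64. All 33 cell cycle genes fell, with a median of -2.29. Erythroid genes fell in 21 of 29 cases, led by the embryonic globin hbbe3, which went from 610 ± 148 to 0.155 ± 0.179 FPKM (SD, n = 4; limma adjusted p = 1.91e-13). The hatching enzymes he1a and he1b fell, with log2 fold changes of -8.94 and -8.08 on the log2(FPKM + 0.5) scale (limma adjusted p = 4.25e-08 and 4.03e-08). The cathepsin L-like genes MGC174155 and LOC100536033 had log2 fold changes of -8.76 and -7.75, and LOC568656, predicted to encode a type-4 ice-structuring protein, fell by 7.34. The genes si:dkey-26g8.4, wu:fa26c03, zgc:174855 and si:dkey-269i1.3 fell too, with log2 fold changes of -8.79, -8.43, -7.30 and -7.22. Tandem copies among these proteases are similar in sequence and could share reads. Camera called 20 of 28 lists for development, 14 up and 6 down, and fry called 23. With an estimated correlation camera called 0, with an adjusted p of 0.0539 for photoreceptors and for xenobiotic response and 0.138 for the exocrine pancreas. The ribosomal protein list, 49 of 77 members down by limma, had 14 down after quantile normalization, and its median lay above that of all genes there (0.10). On replicates 1 to 3 only 14021 genes changed, and with the batch term 15396.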

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

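The tests of developmental age and of scaling at 48 hpf, the tests that account for the batch of replicate 4, and both tests on immediate-early genes were chosen only after the result was seen.

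Values far from the others of their group were looked for with Dixon's ratio at a critical value of 0.829, which chance exceeds in about 1 of 20 groups. Among 28 groups of library measures, 11 held such a value. Raw reads stood apart in replicate 4 of every group, at 49.97 M in control 48 hpf, 40.18 in RFR 48 hpf, 50.16 in control 120 hpf and 48.05 in RFR 120 hpf. Reads after filtering stood apart in RFR 48 hpf replicate 4 (39.6 M) and control 120 hpf replicate 4 (49.23 M). The rRNA share was 3.2% in control 120 hpf replicate 1 and 0.24% in RFR 120 hpf replicate 4, and 91.08% of bases reached quality 30 in control 48 hpf replicate 4. RFR 120 hpf replicate 4 had 21706 genes at 0.5 FPKM or more, and the 10 most abundant genes took 10.79% of the FPKM total in control 120 hpf replicate 2.

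Among 233 groups of values of named genes, 17 held such a value, where 12 come by chance. In control 48 hpf these were sirt3 at 3.05 and rbp4l at 21.97 FPKM in replicate 1, mcm4 at 58.78, aanat2 at 0.71, zgc:92041 at 1.11 and si:dkey-269i1.3 at 143.55 in replicate 2, and plk3 at 15.6 in replicate 4. In RFR 48 hpf they were ccnd1 at 83.33, crygmxl2 at 241.06 and rorab at 4.87 in replicate 1, and blvrb at 17.32 and hmox1a at 8.28 in replicate 2. At 120 hpf they were mcm2 at 9.1 and and3 at 113.91 in RFR replicate 2, nfil3-5 at 9.85 in control replicate 1, he1b at 0.89 in control replicate 2 and socs3b at 10.24 in control replicate 3.

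Of the 18 lists called at either stage, 13 differed in their RFR effect between stages by camera on the interaction. Moving up from 48 to 120 hpf were ribosomal proteins (camera adjusted p = 6.06e-30), the stress axis (0.000191), p53 (0.000346), epidermis (0.0134), sterol synthesis (0.0181), liver (0.0181), inflammation (0.0254) and erythroid cells (0.0375). Moving down were neurons (3.53e-09), cartilage (2.08e-06), lens (0.000346), pigment cells (0.0101) and calcium handling (0.0375). With an estimated correlation 0 of them were called. The 48 hpf median of the ribosomal list depended on scaling.

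At 48 hpf the neuron (median 0.26 log2 units) and lens (0.33) lists were higher in RFR and the ribosomal list lower (-0.16), each with an exact permutation p of 0.114 for its mean over 4 against 4 libraries (0.15, 0.15 and 0.1 with orders kept within replicates 1 to 3 and within replicate 4). Scaling of the libraries is argued against for the neuron and lens lists, which kept at least 0.788 of their medians, but not for the ribosomal list, at -0.038 after quantile normalization; these lists were parted after a joint test had kept 2 of 3. Older RFR embryos cannot be told apart from an RFR effect. The RFR libraries lay 4.31% further along the axis from 48 to 120 hpf (exact permutation p = 0.171). Without RFR replicate 3 this was 2.4% (exact permutation p = 0.371). Without RFR replicate 1 it was 6.6% (exact permutation p = 0.0286, the smallest that 4 against 3 libraries can give). A second age score, computed without the ribosomal, neuron and lens genes, served as a covariate. With it, the highest ratio of a difference to its error was 2.34, for neurons. That ratio passed the bound of 2 set beforehand by less than its own spread, and it was read as open only after it was seen. Wrong labels of control replicate 4 and RFR replicate 1 cannot be told apart either. On the axis from the other controls to the other RFR libraries, control replicate 4 lay at 0.48 and RFR replicate 1 at 0.253. The prediction counted a position of control replicate 4 below the bound of 0.5 as against wrong labels. It was read as open, since 0.48 lay under that bound by less than the libraries' spread. The libraries that set the axis lie near its ends by construction. A library left out of it is drawn toward the middle by their spread, so a position of 0.48 is no sign of wrong labels by itself. Control replicate 4 shares the batch of RFR replicate 4, which helps to set this axis: without RFR replicate 4 in it the position was 0.32, and 0.677 when the replicate 4 difference of 120 hpf was taken off, on either side of the bound.

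At 120 hpf all 21 immediate-early genes looked at, 11 of them in the stress axis list, had the higher mean in RFR, with a median of 0.52 log2 units. The other 20 members of that list had a median of 0.14. The class was picked after members of it had the smallest p in that list, so this contrast is no separate support. Members from the list lay between 0.308 (egr3) and 1.338 (npas4a), and those added from outside it between 0.048 (jun) and 1.191 (egr4). The permutation p below do not allow for this choice. The higher level in RFR did not rest on the separate batch of replicate 4 alone, since the median of the 21 genes was 0.50 in replicates 1 to 3. Each group held 1 library of that batch, so a batch shift common to both groups cancels in this comparison. A chance order of the libraries cannot be told apart from an effect: the exact permutation p over 4 against 4 libraries was 0.0857, two-sided, with replicate 4 lowest in both groups, and with orders kept within replicates 1 to 3 and within replicate 4 it was 0.05, the smallest that these 40 orders can give. RFR lay above control in replicate 4, and in replicates 1 to 3 the lowest RFR library (3.529 log2 units) lay above the highest control (3.306). At 48 hpf 17 of the 21 were higher (exact permutation p = 0.257, or 0.3 within the batches). An effect of RFR stays open. Handling at collection was not recorded in the labels and was not tested.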

How the results depend on the processing

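The fits on replicates 1 to 3 only and with replicate 4 as a batch term were chosen only after the data were seen. With an estimated correlation 0 lists were called at 48 and 0 at 120 hpf. At 48 hpf limma called 2 genes without a filter, 3 at a pseudocount of 0.1, 8 with library weights, 0 at 5 FPKM or more (1588 at an unadjusted p under 0.05) and 0 with only the groups compared (XR_659546.2, adjusted p = 0.28). At 120 hpf it called 4 without a filter. The difference between stages gave 1 gene after quantile normalization, 1 at a pseudocount of 0.1 and 1 on replicates 1 to 3 only. For development 9663 genes changed at 5 FPKM or more, where 12568 were tested; the share rising was 57.9%, 41.6% after quantile normalization and 51.3% after median-ratio scaling. Apart from the filters, which change the genes tested, the cause was not tested.

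Leaving out each library in turn gave 1 to 389 genes at 48 hpf, 0 to 0 at 120 hpf (718 to 1294 at an unadjusted p under 0.05), 0 to 1 for the difference between stages and 14550 to 14763 for development. It gave 8 to 11 lists at 48 and 7 to 14 at 120 hpf. The highest count at 48 hpf came without RFR replicate 1, and the lowest list count at 120 hpf without control replicate 2 or RFR replicate 2. The neuron, lens, calcium, ribosomal, cell cycle and heat shock calls at 48 hpf and the stress axis, p53 and cartilage calls at 120 hpf held in all 14 settings tried for lists at the preset correlation. The filters, pseudocounts, fit without a trend and library weights were not tried for lists. Without single libraries the medians of the cell cycle (-0.049), heat shock (-0.067) and p53 (0.025) lists came closer to 0 by over 1.5 times, and that of the stress axis list rose to 0.50. Scaling also moved medians closer to 0: the ribosomal median went from -0.16 to -0.038 after quantile normalization, and the calcium median from 0.12 to 0.069 after median-ratio scaling. Of 2441 values of named genes under alternatives, 2416 lay on the same side of the threshold, 24 were now past it, 1 no longer was and 0 changed direction. These genes were picked by p or size of change in the same libraries, and most lay far from the threshold. The counts therefore say little about how firm the RFR differences are.

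With the replicate block, limma called 1 gene at 120 hpf, LOC100007069 (log2 fold change 1.79, adjusted p = 0.0131), and the counts at 48 hpf (1), for the difference between stages (0, with 1642 at an unadjusted p under 0.05) and for development (15357) stayed within 1.5 times. Whether the numbers pair the samples is not settled. Within a stage, deviations of same-numbered libraries correlated from -0.111 to 0.308, and 4 of 8 pairs correlated best with their own number. These were replicates 3 and 4 at both stages. At 120 hpf the coefficients of replicates 1 to 4 were all positive (0.18, 0.0578, 0.276 and 0.273). There, control replicates 1 and 2 correlated best with RFR replicates 2 and 1. For the median gene an estimated RFR change had to pass about 1.24-fold to reach an unadjusted p under 0.05 in limma. True changes of that size would often be missed. In the simulations 43% (48 hpf) and 56% (120 hpf) of 1.5-fold changes were recovered after adjustment.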

Other observations

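The tests of Gene Ontology terms, of the splits with replicate 4 as a batch term and of the other variant of the noncoding transcript were chosen only after the result was seen.

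Among 569 Gene Ontology biological process terms, camera called 46 at 48 hpf, 12 higher and 34 lower in RFR, and 0 with an estimated correlation. Translation (132 genes) had a median of -0.093 log2 units (camera adjusted p = 4.37e-13; adjusted p = 0.633 with an estimated correlation) and cholesterol biosynthetic process (11 genes) of -0.35 (4.25e-05; adjusted p = 0.633 with an estimated correlation). Homophilic cell adhesion (93 genes) had 0.20 (1.26e-05, and 0.845 with an estimated correlation) and synapse organization (11 genes) 0.30 (0.00238, and 0.781 with an estimated correlation). A term with a neural name went the other way: neuron projection regeneration (10 genes) had -0.38 (camera adjusted p = 4.25e-05, and 0.633 with an estimated correlation). Cholesterol efflux had the same size and median (10 genes, -0.38), and cholesterol homeostasis those of cholesterol biosynthetic process (11 genes, -0.35). These terms may share genes, and their overlap was not tested. Neuron projection regeneration is therefore not read as a result on neural genes. The fixed sterol synthesis list (26 genes) had a median of -0.10. At 120 hpf camera called 4 terms: potassium ion import (19 genes, median 0.082), DNA replication (54 genes, -0.11), fin development (18 genes, -0.087) and ribosomal large subunit assembly (10 genes, 0.091). Their adjusted p was 0.017, 0.017, 0.017 and 0.0408, and 0.964 for each with an estimated correlation.

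Other splits of the 8 libraries of a stage into 4 against 4 were fitted in the same way. At 48 hpf, 8 of 35 splits gave as many genes as the real 1, with 875 as the highest other, so chance cannot be excluded. The same holds for the 2180 genes at an unadjusted p under 0.05 (3 of 35 splits, highest other 3406) and for the 10 lists (19 of 35, highest other 17). The split with 875 genes puts RFR replicate 1 with control replicates 1 to 3 and control replicate 4 with RFR replicates 2 to 4, which points to a structure of these libraries that does not follow the labels. It also has both replicate 4 libraries, the separate batch, on one side. With replicate 4 as a batch term it gave 697 genes where the real split gave 1 (6 of 35 splits gave as many, so chance cannot be excluded), so a batch difference common to both stages is not the whole of this structure. Without RFR replicate 1, 2 of 35 splits of the 7 libraries gave as many as the real 389 genes, and the highest other, 578, again put control replicate 4 with RFR replicates 2 to 4 (412 and 416 genes with the batch term), so the 389 genes are not shown to follow RFR. Among them, 19 of 64 lens, 11 of 59 neuron and 5 of 59 photoreceptor genes rose, where 1.52% of all genes did, and 4 of 33 neural progenitor genes fell.

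At 120 hpf the 952 genes at an unadjusted p under 0.05 were reached by 23 of 35 splits (highest other 3879) and the 12 lists by 19 of 35 (highest other 17), so chance cannot be excluded. The split with 3879 genes parts replicates 1 and 2 of both groups from replicates 3 and 4, several times the real count, which points to a structure by replicate number; with the replicate block 995 genes had an unadjusted p under 0.05 and 1 was called. Where limma called 0 genes, the count of calls says nothing about chance, since any split reaches it: 35 of 35 splits at 120 hpf (highest other 6) and 100 of 100 drawn for the difference between stages (highest other 435). For development, 1 of 35 splits, the real one, gave as many as 15227 genes, with 0 as the highest other. That share is the smallest that these splits can give (0.0286). Every other split mixes both stages within a group, which widens the spread. The 0 calls there therefore do not show what chance alone would give.

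The transcript XR_659546.2 was present in all control 48 hpf libraries and listed at 0 in all RFR libraries of that stage. The other variant of the locus differed by 0.227 FPKM (upper 95% limit 1.01), where 2.91 FPKM were lost. It stood at 0.515 ± 0.31 in controls and 0.742 ± 0.563 in RFR (SD, n = 4). FPKM is scaled to transcript length and the lengths of the variants are not given here. Reads moved to the other variant therefore cannot be excluded. Chance among many features could account for it: 3 of 35 splits gave as many features at 0 in 4 libraries and above the minimum in the other 4 (real 2, highest other 3). An effect of RFR stays open.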
